A study of Mus musculus with 4 samples.

How the data were processed

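RNA sequencing was performed on 4 samples of mouse neural stem cells, 2 heterozygous and 2 null for Dgcr8. Per the labels' protocols, total RNA was extracted with a commercial kit, its integrity was checked on a bioanalyzer, and paired-end libraries were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat2 version 2.0.6 and the mm10 mouse genome build were used. The counting tool, the gene annotation and the strand setting are not given in the sources used here.

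Samples were grouped by the genotype in their titles. The authors deposited 1 table of counts per gene symbol. Its 4 value columns were named by library codes that matched no sample title, description or characteristic. All 4 columns were left out, and 0 were used, because a column was accepted only where its name matched a label. A test of null against heterozygous cells, gene list tests and a test of microRNA seed matches in 3′ untranslated regions were planned before the data were examined. None was run, since each needs the genotype of every library. When the table was first inspected, the similarity between its columns and the Dgcr8 counts were seen. These were not used to assign genotypes.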

Results

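The study examined cultured mouse neural stem cells derived from mid-gestation embryonic brain. Neural stem cells are self-renewing progenitors that can give rise to neurons and glia. Transcripts were measured by paired-end RNA sequencing of total RNA in 4 samples. Of these, 2 samples were labelled heterozygous for Dgcr8 and 2 were labelled null. Dgcr8 encodes the RNA-binding partner of Drosha in the Microprocessor, the nuclear complex that cuts primary microRNA transcripts into hairpin precursors.

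The design implied a single comparison, that of null with heterozygous cells, which asks how the transcript profile of neural stem cells differs when Dgcr8 is absent. The comparison was not made here. The count table carried 4 columns of values, and each heading held a library code. Some headings, but not all, had a further part before the code. The codes of all 4 columns were absent from the sample and series labels used here, so no column could be assigned to a sample or to a genotype by its name. The labels used here do not say that the order of the columns follows the order of the samples. The level of any gene in the columns, Dgcr8 included, is part of what the comparison would measure. No column was assigned on either basis. No gene is therefore reported as higher or lower in null cells, and no expression value, fold change or p-value is given for any sample or group.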

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

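No paired analysis was possible because the columns of the count table carry no replicate number and no genotype. The sample titles do carry replicate numbers, but they do not say that samples with equal numbers share a litter or a culture day. Other library scaling, other tests, other filters on low counts, leaving out each library and other definitions of microRNA sites were not run. A further gene set test was planned and not run either. The effect of any of these on the comparison of null with heterozygous cells cannot be seen without the genotype of each library. Matching of the column names to the labels was repeated with 3 looser rules chosen after the table was seen: the library code alone, either part of the name, and the digits of the code. Each matched 0 of the 4 columns, as did the whole name. These counts are not separate checks, since labels without the digits cannot hold the code or the whole name. Only a part of the name outside the code, where there was one, added a further lookup.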
